A study of Mus musculus with 24 samples.

How the data were processed

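Total RNA of 24 samples of a V6.5 mouse embryonic stem cell line with a BRD2 degron was sequenced. Per the labels, mES cells were kept in 2i medium with LIF, and EB formed in medium without LIF. The labels do not say when within EB culture IAA was added, nor whether the 3 samples of a group were separate cultures. The p-values therefore measure only the spread between these samples. Groups were read from the labels: mES, EBd2, EBd3 and EBd4, each with Dox alone or with Dox and IAA, 3 libraries each. Other assays of the series were not analysed here.

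Per the labels, reads were aligned to mm10 with STAR 2.5.3a, counted per gene with featureCounts 1.5.2 and fitted with DESeq2. The version of DESeq2, the strandedness and the annotation's version are not given. The authors deposited a table for each of the 4 stages, with 35742 genes each. The signal values per library are counts that the authors divided by 1 DESeq2 size factor per library, as the deposited values show: all positive values (100%) were whole reads within 1e-06 when multiplied by a factor. The deposited mean equals the mean over the 24 libraries, so the factors were made jointly and the 4 tables can be compared. The authors also deposited the log2 fold change and its SE, which DESeq2 made per the file headers. The deposited score is the Wald statistic of DESeq2, per the file headers. The deposited p-value columns hold the DESeq2 p and its adjusted form, per the file headers. A text column gives the authors' calls, which have an adjusted p below 0.05 and an absolute log2 fold change above 1. These columns were used for comparison alone. Of the genes, 14339 have no symbol and hold 1.12% to 1.32% of the reads, 61 share a symbol with another, and 35652 were found in GENCODE M21, from which positions, exonic length and genomic span were taken.

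The test planned before the data were examined was for counts, with edgeR. Since the tables hold size-factor-normalized values, the test set for that case was used: limma (3.58.1, trend) on log2 of the value plus 1, for genes with a mean of at least 1, with Benjamini-Hochberg adjustment at 0.05. Each stage was fitted alone for IAA against Dox. The 12 Dox libraries were fitted together for the stages against mES, and all 24 for the difference of the IAA effect between stages. Gene lists were tested with camera of limma at an inter-gene correlation of 0.01, for 21 lists with at least 4 measured members. A 22nd list, the BET family, was not tested as a list. List tests were run for IAA against Dox and for the differences between stages, and Dox stages have counts of members alone. Of 377 list members, 7 were not found by symbol. Lists, comparisons and alternatives were chosen before the data were examined, except those named below or in the closing parts as chosen later.

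Genes were named by a rule: the 6 largest log2 fold changes each way with adjusted p below 0.05, a CPM of at least 5 in the higher group and no overlap between the libraries of the groups. Genes named Gm and a number, Rik clones, genes annotated as pseudogenes and IDs without a symbol were skipped. The BET family and up to 3 members per list with the smallest adjusted p were added. For Dox stages and differences between stages it was 4 each way and 4 per list, and for genes changed in all stages 5 each way. For differences between stages the CPM was that of the highest group of all, and libraries were allowed to overlap. Genes changed in all stages were named without a CPM or overlap requirement. Some genes that this rule names are not reported here. The value of T in EBd4 was added after it was seen.

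Recovered whole reads per library ranged from 7819522 to 15732767, of which 0.831% to 1.29% were mitochondrial, and the 10 highest genes held 2.89% to 4.17%. The mitochondrial share was higher in every IAA library than in every Dox library in EBd2 (0.959% to 1.03% against 0.831% to 0.892%) and EBd3 (1.25% to 1.26% against 1.14% to 1.19%). So was the share of the 10 highest genes in mES (3.84% to 4.04% against 3.51% to 3.53%), EBd2 (3.22% to 3.38% against 2.89% to 3.05%) and EBd3 (3.67% to 3.85% against 3.50% to 3.65%). All 24 pairs of libraries within groups differed by more than sampling noise (chi-square per degree of freedom from 1.12 to 5.35), with the widest pair among EBd4 IAA. EBd2 Dox 3 stood apart from Dox 1 and Dox 2 (4.49 and 3.77), which were closer to each other (1.29). Tested on simulated data, limma recovered 69 of 100 genes changed 1.5-fold and 92 of 100 changed 2-fold in mES. It recovered 80 and 91 in EBd2, 70 and 88 in EBd3, and 63 and 83 in EBd4, with 4, 12, 4 and 14 calls among unchanged genes. For the Dox stages it recovered 65 and 83, 59 and 84, and 61 and 84, and for the differences between stages 59 and 68, 54 and 63, and 49 and 68. For genes changed in all stages it recovered 56 and 71. Of 21 lists shifted 1.5-fold, camera recovered 19, 21, 21 and 21 in the 4 stages, and 19, 21, 18 and 16 with an estimated correlation. Lists not shifted were called in 0.959%, 1.43%, 0.952% and 4.29% of tests. Simulated genes were drawn independently, so these shares do not show how often the test calls lists of correlated genes. When the real libraries were regrouped otherwise, a median of 2, 4, 2 and 5 of the 21 lists were called in the 4 stages. A span slope set at -0.2 was recovered as -0.20, -0.21, -0.21 and -0.20, and a slope of 0 as values from -0.01 to 0.00.

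The alternatives were edgeR (4.0.16) with RLE scaling and DESeq2 (1.42.0) on the recovered reads, no filter, a pseudocount of 0.1 without filter, a block by replicate number, an absolute log2 fold change of at least 1, all 24 libraries in 1 fit, a list correlation estimated per list, and each library left out in turn. For the Dox stages the 6 libraries of the 2 groups were also fitted alone. Added after seeing the data were edgeR with TMM scaling, TMM scaling followed by limma, and a pseudocount of 0.1 with the filter kept. The genomic span comparison was also chosen after seeing the data. Other splits of the libraries were counted, 10 for 3 against 3 and 100 drawn for the larger designs. Tables were read in R 4.3.3 with the data.table package (1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.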

Results

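RNA was sequenced from V6.5 mouse embryonic stem (mES) cells carrying a BRD2 degron, a tag through which a protein can be removed by adding auxin. All cultures received doxycycline (Dox, 1 µg/ml) for 18 h, and the treated ones also received the auxin indole-3-acetic acid (IAA, 500 µM) for 24 h. Cells were taken as mES cells or as embryoid bodies (EB), aggregates in which stem cells differentiate, on day 2, 3 or 4. The 8 groups (4 stages, each with Dox or with IAA) held 3 libraries each, 24 in all. Total recovered reads per library ranged from 11102416 to 14317039 in mES and from 11005217 to 15732767 in EBd2. They ranged from 7819522 to 9416260 in EBd3 and from 7941180 to 10598075 in EBd4. In EBd4 every IAA library had more reads (9007143 to 10598075) than every Dox library (7941180 to 8120480). Depth and IAA therefore go together in that stage. Levels below are mean size-factor-normalized counts ± SD over the 3 libraries of a group (n = 3), given as Dox to IAA. Changes are log2 fold changes ± SE of IAA over Dox from limma. "Rose" and "fell" mean past an adjusted p of 0.05. Gene positions are on mm10 from GENCODE M21.

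The targeted gene was measured first. Its RNA does not show whether the protein was degraded, since the degron acts on the protein. Brd2 RNA (ENSMUSG00000024335, chromosome 17, 34112023 to 34122634) rose with IAA in every stage. It went from 4497 ± 99.2 to 8243 ± 204 in mES (log2 0.87 ± 0.02) and from 7409.7 ± 283 to 11630.3 ± 583 in EBd2 (0.65 ± 0.04). It went from 4421 ± 254 to 5765 ± 233 in EBd3 (0.38 ± 0.04) and from 3015 ± 137 to 4215 ± 365 in EBd4 (0.48 ± 0.06). Hexim1, which codes for an inhibitor of the elongation kinase P-TEFb, also rose in every stage, with log2 fold changes of 0.98, 0.70, 0.66 and 0.54. Larp7, which stabilises the 7SK RNA of the same inhibitory complex, fell in every stage (-0.52, -0.86, -0.40 and -0.75). The BET gene Brd3 rose in mES (0.19 ± 0.03) and in EBd3 (0.15 ± 0.04). The EBd3 call was lost by DESeq2, with a smaller constant under the log, and without any of the libraries IAA 1, IAA 2, Dox 1, Dox 2 or Dox 3. In EBd2 its limma value was 0.12 ± 0.05 (adjusted p = 0.109, past the threshold without Dox 3 and with TMM scaling) and in EBd4 -0.01 ± 0.05. The germ-cell gene Brdt was not past the threshold in any stage. Its EBd2 limma value was -0.38 ± 0.15 (adjusted p = 0.0534, past the threshold without IAA 1, without Dox 3 or without the filter on low values).

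**Figure D1:**
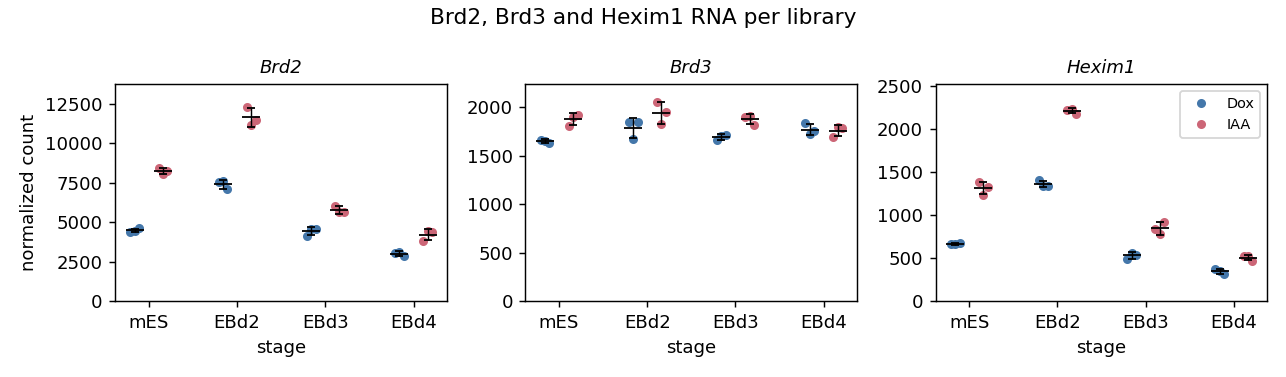
Normalized counts of Brd2, Brd3 and Hexim1 (vertical axis, from 0) in each stage (horizontal axis). Points are libraries, bars are the mean ± SD of 3 libraries with Dox (blue) or IAA (red), and the IAA points of Brd2 and Hexim1 lie above the Dox points in all 4 stages.

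The first comparison asked which RNAs change in mES cells when IAA is added. The strongest fall was that of Porcn, the acyltransferase that prepares Wnt proteins for secretion (ENSMUSG00000031169, chromosome X, 8193848 to 8206525; from 149 ± 3.03 to 11.1 ± 0.805, log2 -3.63 ± 0.16). The Nodal antagonist gene Lefty1 (ENSMUSG00000038793, chromosome 1, 180935022 to 180938400) fell from 1118 ± 21.6 to 179.7 ± 11.1 (-2.63 ± 0.05). The others of the 6 largest falls were the sodium channel gene Scn3a (-2.85), Enpp3 (-2.73), Il17d (-2.63) and Crmp1 (-2.57). The strongest rises were Tmem132d (from 12.9 ± 2.49 to 72 ± 0.541, 2.40 ± 0.20), the muscarinic receptor gene Chrm1 (2.31) and the glutathione-degrading enzyme gene Chac1 (1.89). The stress-induced transcription factor gene Atf5 (ENSMUSG00000038539, chromosome 7, 44812256 to 44816658) rose from 558 ± 4.36 to 1940.3 ± 74.4 (1.79 ± 0.04), and Il17f (1.72) and Grm4 (1.67) rose too. In all, 7821 of 20865 tested genes changed, 3618 up and 4203 down. Of these, 247 rose and 1008 fell by at least 2-fold.

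Members of the integrated stress response, the ATF4 programme of amino acid and translation stress, rose in mES. Of 18 measured stress response genes, 13 rose and 3 fell (13 and 3 adjusted over the list alone). Chac1, Atf4 (from 2682 ± 81.5 to 4380.1 ± 97.9) and Ddit4 (1.59) were among the rises. Stress response genes gave adjusted p = 2.28e-10 in the list test and adjusted p = 0.135 with an estimated correlation. Of 30 measured Hox genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone). They did so from low levels, with Hoxd9 going from 14.7 ± 2.43 to 52.3 ± 3.64 and Hoxd13 from 10.8 ± 0.539 to 43.9 ± 2.82. Hox genes gave adjusted p = 0.000303 in the list test and adjusted p = 0.135 with an estimated correlation. Of 41 measured Pol II factors, 21 rose and 1 fell (23 and 1 adjusted over the list alone). Hexim1 and Polr2a (from 4559 ± 97.8 to 6051 ± 205), the gene of the catalytic subunit, rose, and Larp7 fell. Pol II factors gave adjusted p = 3.6e-05 in the list test and adjusted p = 0.279 with an estimated correlation. Of 14 measured naive pluripotency genes, 9 rose and 2 fell (9 and 3 adjusted over the list alone). The rises included Tfcp2l1 (from 6814 ± 360.5 to 9217 ± 144), Klf4 (0.50) and Zfp42 (0.29), the latter pair not past the threshold in a joint fit of all 24 libraries. Naive pluripotency genes gave adjusted p = 5.76e-05 in the list test and adjusted p = 0.279 with an estimated correlation. Most core pluripotency genes fell in mES, and the list did not pass with an estimated correlation. Of 12 measured core pluripotency genes, 3 rose and 7 fell (3 and 7 adjusted over the list alone). Lin28a (from 2111 ± 60.2 to 841 ± 15.3) and Utf1 (from 1383 ± 44 to 637 ± 29.7) fell and Trim28 rose (0.32). Core pluripotency genes gave adjusted p = 0.0248 in the list test and adjusted p = 0.279 with an estimated correlation. Of 21 measured p53 targets, 2 rose and 13 fell (3 and 13 adjusted over the list alone). The falls included Ccng1 (from 1034 ± 13.6 to 666 ± 37.1) and Eda2r (-1.13). Targets of p53 gave adjusted p = 0.00227 in the list test and adjusted p = 0.135 with an estimated correlation.

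The other 15 lists were not past the threshold in mES (adjusted p from 0.0613 to 0.949), although single members were. Of 11 measured Nodal targets, 3 rose and 5 fell (3 and 5 adjusted over the list alone). Lefty1 and Lefty2 (from 5228 ± 141 to 2313 ± 189.7) were among the falls. Of 12 measured formative epiblast genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone). The falls included the DNA methyltransferase genes Dnmt3b (from 1047 ± 54.1 to 320.3 ± 18.6) and Dnmt3a (from 939 ± 12 to 429 ± 25.7). Of 15 measured FGF and ERK targets, 3 rose and 5 fell (3 and 5 adjusted over the list alone). Spry4 (from 38.2 ± 4.86 to 6.99 ± 2.07) and Etv4 (-1.31) were among the falls. Definitive endoderm genes had 1 up and 4 down of 8 (1 and 4 adjusted over the list alone), with Trh falling from 1024 ± 79.1 to 184 ± 0.925. Trophoblast genes had 1 up and 4 down of 8 (1 and 4 adjusted over the list alone). Neuroectoderm genes had 5 up and 1 down of 15 (5 and 2 adjusted over the list alone). Wnt targets had 2 up and 3 down of 13 (2 and 4 adjusted over the list alone). Germline genes had 2 up and 3 down of 15 (2 and 3 adjusted over the list alone), Dazl among the rises (1.18). Blood and endothelium genes had 2 up and 2 down of 11 (2 and 2 adjusted over the list alone). Primitive endoderm genes had 3 up and 1 down of 13 (3 and 1 adjusted over the list alone). Primitive streak genes had 2 up and 1 down of 8 (2 and 3 adjusted over the list alone). Mesoderm genes had 1 up and 1 down of 14 (1 and 1 adjusted over the list alone). Fibroblast genes had 0 up and 2 down of 4 (0 and 2 adjusted over the list alone). 2-cell-like genes had 0 up and 1 down of 9 (0 and 0 adjusted over the list alone). Targets of the aryl hydrocarbon receptor (AhR), which is activated by aromatic compounds, had 1 up and 2 down of 6 (1 and 2 adjusted over the list alone). The median, mean and test of a list differed in sign in mES for formative epiblast, primitive streak, blood, primitive endoderm and AhR targets.

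In EBd2, the same question was asked of cells leaving naive pluripotency. The strongest falls included the titin gene Ttn (ENSMUSG00000051747, chromosome 2, 76703980 to 76982547; from 1048 ± 100.5 to 117 ± 2.93, log2 -3.14 ± 0.08) and the neuronal adhesion gene Nrcam (from 124 ± 10.6 to 19.4 ± 2.45, -2.62 ± 0.16). Ccdc187 (-3.23), Trim67 (-3.03), Vwa3b (-2.77) and Egfl6 (-2.57) were the others. Atf5 had the largest rise (from 785 ± 11.9 to 3416 ± 100.2, 2.12 ± 0.05). It was followed by Tcf15, a transcription factor gene of primed epiblast (from 181 ± 26.7 to 632 ± 16.4, 1.81 ± 0.09), and the homeobox gene Gbx2 (1.59). The collagen prolyl hydroxylase gene P4ha1 (1.53), Cdk5r2 (1.39) and the eye and neural gene Pax6 (1.37) rose too. Of 22076 tested genes, 2954 rose and 3684 fell, 6638 in all, with 205 rises and 1137 falls of at least 2-fold. Without Dox 3, which stood apart from the other Dox libraries, the count was 7248.

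Several markers of naive pluripotency were lower with IAA in EBd2 and several of the epiblast and neuroectoderm higher. Of 14 measured naive pluripotency genes, 0 rose and 8 fell (0 and 9 adjusted over the list alone). Esrrb fell from 300.3 ± 21.7 to 139.5 ± 8.47, Nanog from 526 ± 53 to 259 ± 28.5 and Fbxo15 by a log2 fold change of -1.11. Naive pluripotency genes gave adjusted p = 1.98e-05 in the list test and adjusted p = 0.142 with an estimated correlation. Of 13 measured formative epiblast genes, 10 rose and 1 fell (10 and 2 adjusted over the list alone). Tcf15, Dnmt3b (from 21015 ± 308 to 28118 ± 949) and Fgf5 (from 403 ± 58.4 to 669 ± 15.9) were among the rises. Formative epiblast genes gave adjusted p = 4.19e-07 in the list test and adjusted p = 0.142 with an estimated correlation. Of 19 measured neuroectoderm genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone). Pax6, Tubb3 (from 319.9 ± 23 to 729 ± 29) and Nes (0.76) rose. Neuroectoderm genes gave adjusted p = 2.07e-05 in the list test and adjusted p = 0.142 with an estimated correlation. Of 18 measured stress response genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone). The rises included the amino acid synthesis genes Asns (from 1547 ± 74.5 to 2572 ± 61.3), Psat1 (0.60) and Phgdh (0.56). Stress response genes gave adjusted p = 4.19e-07 in the list test and adjusted p = 0.142 with an estimated correlation. Of 16 measured FGF and ERK targets, 7 rose and 2 fell (8 and 2 adjusted over the list alone). Dusp4 (0.49) and Spred3 (0.36) rose. FGF and ERK targets gave adjusted p = 0.0119 in the list test and adjusted p = 0.142 with an estimated correlation. Of 32 measured Hox genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone). Their levels stayed low, with Hoxa5 going from 3.53 ± 0.920 to 16.1 ± 3.76. Hox genes gave adjusted p = 0.0266 in the list test and adjusted p = 0.142 with an estimated correlation. Of 41 measured Pol II factors, 14 rose and 6 fell (14 and 6 adjusted over the list alone). Hexim1 rose, and Larp7 and Aff1 (-0.90) fell. Pol II factors gave adjusted p = 0.0462 in the list test and adjusted p = 0.142 with an estimated correlation. Pol II factors were lost without IAA 2, IAA 3, Dox 2 or Dox 3, and Hox genes without IAA 2 or Dox 3.

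The list tests past the threshold and pointing down in EBd2 included those of germline and 2-cell-like genes. Of 16 measured germline genes, 0 rose and 11 fell (0 and 13 adjusted over the list alone). Taf7l (from 339.8 ± 46.3 to 114 ± 12.3), Zcwpw1 (from 1129 ± 118 to 592 ± 21.3) and Sycp2 (-1.32) fell. Germline genes gave adjusted p = 4.19e-07 in the list test and adjusted p = 0.142 with an estimated correlation. Of 13 measured 2-cell-like genes, 0 rose and 9 fell (0 and 9 adjusted over the list alone). Zscan4d (-0.87) and Zscan4c (-0.89) fell, close paralogs whose reads cannot always be told from each other. 2-cell-like genes gave adjusted p = 2.07e-05 in the list test and adjusted p = 0.158 with an estimated correlation. Of 22 measured p53 targets, 1 rose and 14 fell (2 and 16 adjusted over the list alone). Zmat3 (from 2909 ± 233 to 1611 ± 98.3), Ckap2 (-0.51) and Aen (-0.43) fell. Targets of p53 gave adjusted p = 1.47e-06 in the list test and adjusted p = 0.165 with an estimated correlation. Of 11 measured Nodal targets, 2 rose and 6 fell (2 and 6 adjusted over the list alone). Gdf3 (from 1649 ± 104 to 564 ± 29.9), Nodal itself (from 1378 ± 153 to 761 ± 7.55) and Lefty2 (-1.05) fell. Nodal targets gave adjusted p = 0.00148 in the list test and adjusted p = 0.142 with an estimated correlation. Of 16 measured Wnt targets, 1 rose and 8 fell (1 and 9 adjusted over the list alone). Axin2 (from 329.9 ± 46.4 to 109 ± 6.50) and Lef1 (-0.75) fell. Wnt targets gave adjusted p = 0.0106 in the list test and adjusted p = 0.208 with an estimated correlation. Of 10 measured fibroblast genes, 0 rose and 7 fell (0 and 8 adjusted over the list alone). They are expressed at low levels, as in the fall of Dcn (-1.98). Fibroblast genes gave adjusted p = 0.00148 in the list test and adjusted p = 0.142 with an estimated correlation. Of 13 measured blood and endothelium genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone). Tek, an angiopoietin receptor gene, fell from 271 ± 29.1 to 83.4 ± 13.8. Blood and endothelium genes gave adjusted p = 0.0275 in the list test and adjusted p = 0.142 with an estimated correlation. Of 13 measured primitive streak genes, 1 rose and 4 fell (1 and 6 adjusted over the list alone). Wnt3 (-1.34) and Wnt8a (-1.06) fell. Primitive streak genes gave adjusted p = 0.0404 in the list test and adjusted p = 0.142 with an estimated correlation. That call was lost without IAA 2 or Dox 3.

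The remaining 6 lists were not past the threshold in EBd2, with adjusted p from 0.0961 to 0.962. Core pluripotency genes had 2 up and 5 down of 12 (2 and 6 adjusted over the list alone), Sox2 among the rises (0.67). Mesoderm genes had 1 up and 1 down of 15 (1 and 1 adjusted over the list alone). Primitive endoderm genes had 3 up and 3 down of 14 (3 and 4 adjusted over the list alone). Definitive endoderm genes had 1 up and 2 down of 10 (1 and 2 adjusted over the list alone). Trophoblast genes had 2 up and 3 down of 10 (3 and 4 adjusted over the list alone). AhR targets had 2 up and 2 down of 9 (2 and 2 adjusted over the list alone), Nqo1 among the rises (0.66). The median, mean and test differed in sign for mesoderm, primitive endoderm, trophoblast and AhR targets.

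In EBd3, most Nodal targets fell. Of 10 measured Nodal targets, 0 rose and 7 fell (0 and 8 adjusted over the list alone). Lefty1 fell from 2939.8 ± 295 to 1033 ± 107 (log2 -1.51 ± 0.06) and Gdf3 from 673 ± 39.4 to 256 ± 28.4, and the co-receptor gene Tdgf1 fell as well (-0.54). Nodal targets gave adjusted p = 6.97e-20 in the list test and adjusted p = 0.0196 with an estimated correlation. The largest single falls were Nrcam (-2.56), the glypican gene Gpc6 (from 61.4 ± 2.39 to 14.3 ± 1.62), Zbtb20 (from 119 ± 26.2 to 28.2 ± 3.09) and the potassium channel partner gene Dpp6 (-2.04). Phactr1 (-1.72) and Ctnnd2 (-1.70) came next. Among the largest rises were the ERK phosphatase gene Dusp4 (from 555 ± 13.1 to 1228 ± 233, 1.13 ± 0.08) and the quinone reductase gene Nqo1 (from 454 ± 33.4 to 857 ± 88.5, 0.91 ± 0.07). Nefh (0.93), Ap3m2 (0.88) and Dcaf12l1 (0.81) were others. In total 2245 of 21304 tested genes changed, 899 up and 1346 down, of which 26 and 264 by at least 2-fold. The count was 1214 by DESeq2, and 1321 without IAA 1, 1274 without Dox 1, 1202 without Dox 2 and 1463 without Dox 3.

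Some AhR targets rose in EBd3, and the list did not pass with an estimated correlation. Of 8 measured AhR targets, 3 rose and 0 fell (3 and 0 adjusted over the list alone). They were Nqo1, Tiparp (ENSMUSG00000034640, chromosome 3, 65528410 to 65555518; from 696 ± 48 to 1061 ± 68.4) and Cyp1b1 (from 6.98 ± 1.59 to 23.7 ± 3.95). AhR targets gave adjusted p = 0.00324 in the list test and adjusted p = 0.156 with an estimated correlation. Of 16 measured FGF and ERK targets, 4 rose and 0 fell (5 and 2 adjusted over the list alone). Dusp4, Spry4 (from 389.9 ± 25.2 to 645 ± 104) and Spred1 (0.22) rose. FGF and ERK targets gave adjusted p = 0.021 in the list test and adjusted p = 0.193 with an estimated correlation. Of 16 measured germline genes, 0 rose and 5 fell (0 and 9 adjusted over the list alone). Ddx4, a gene of germ cells, fell from 393 ± 21.1 to 231 ± 29.4. Germline genes gave adjusted p = 2.78e-05 in the list test and adjusted p = 0.0805 with an estimated correlation. Of 12 measured 2-cell-like genes, 0 rose and 1 fell (0 and 3 adjusted over the list alone). 2-cell-like genes gave adjusted p = 0.0213 in the list test and adjusted p = 0.468 with an estimated correlation. Of 9 measured fibroblast genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone). Dcn (-1.48) fell. Fibroblast genes gave adjusted p = 0.0345 in the list test and adjusted p = 0.365 with an estimated correlation. Of 12 measured core pluripotency genes, 2 rose and 3 fell (2 and 5 adjusted over the list alone). Gdf3 and Tdgf1 fell and Trim28 rose (0.19). Core pluripotency genes gave adjusted p = 0.023 in the list test and adjusted p = 0.468 with an estimated correlation. Of 22 measured p53 targets, 1 rose and 4 fell (1 and 4 adjusted over the list alone). Bbc3 (-0.44) fell. Targets of p53 gave adjusted p = 0.041 in the list test and adjusted p = 0.605 with an estimated correlation. With 8 lists past the threshold in all, 5 were left without Dox 2. Core pluripotency was lost without IAA 2 or Dox 2, fibroblast genes without IAA 3 or Dox 1, 2-cell-like genes without IAA 1 or Dox 2, and p53 targets without IAA 1, IAA 2, Dox 2 or Dox 3.

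The remaining 13 lists were not past the threshold in EBd3, with adjusted p from 0.116 to 0.836. Naive pluripotency genes had 1 up and 3 down of 14 (1 and 3 adjusted over the list alone). Formative epiblast genes had 1 up and 1 down of 13 (1 and 1 adjusted over the list alone). Primitive streak genes had 0 up and 3 down of 11 (0 and 3 adjusted over the list alone), Fgf8 among the falls (-1.34, not past the threshold in a joint fit of all 24 libraries). Blood and endothelium genes had 0 up and 1 down of 14 (0 and 1 adjusted over the list alone), Tek being the fall (-1.67). Primitive endoderm genes had 0 up and 1 down of 13 (1 and 4 adjusted over the list alone). Definitive endoderm genes had 1 up and 0 down of 9 (1 and 0 adjusted over the list alone). Neuroectoderm genes had 1 up and 0 down of 19 (1 and 0 adjusted over the list alone), Tubb3 being the rise (0.57). Hox genes had 1 up and 0 down of 24 (1 and 0 adjusted over the list alone). Wnt targets had 1 up and 0 down of 15 (1 and 0 adjusted over the list alone). Pol II factors had 6 up and 4 down of 41 (7 and 5 adjusted over the list alone). Stress response genes had 3 up and 1 down of 18 (4 and 2 adjusted over the list alone). Mesoderm genes had 0 up and 0 down of 14 (0 and 0 adjusted over the list alone). Trophoblast genes had 0 up and 0 down of 10 (0 and 0 adjusted over the list alone). The median, mean and test differed in sign for naive pluripotency, definitive endoderm and Wnt targets.

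In EBd4, some genes of the primitive streak were lower with IAA, with a wide spread between IAA libraries. The largest fall was that of the endoderm factor gene Foxa2 (ENSMUSG00000037025, chromosome 2, 148042877 to 148046969; from 135 ± 43.2 to 26.9 ± 28.2, log2 -3.07 ± 0.71). Fgf8 (from 932 ± 218 to 271 ± 241, -2.18 ± 0.44) and Wnt3 (from 139.9 ± 41.3 to 45.3 ± 37.9), genes of the streak, fell too. Among the 6 largest were also Ism2 (-2.27), the protocadherin gene Fat3 (from 150.3 ± 29.2 to 33.2 ± 5.80, -2.14 ± 0.19) and Nrcam (-2.07). The largest rises were Lmx1b (1.64), the Notch ligand gene Dll1 (1.48), Fos (1.46), Igfbp5 (1.42), Gadd45g (1.41) and Myl3 (1.39). In all 2173 of 21170 tested genes changed, 993 up and 1180 down, of which 76 and 164 by at least 2-fold. The count was 1413 by DESeq2, 3425 with the spread taken from all 24 libraries, and 887 without IAA 2, 776 without Dox 1 and 837 without Dox 2. Foxa2, Fgf8 and Wnt3 were past the threshold neither by edgeR nor by DESeq2, and Fos not by edgeR. Foxa2 and Wnt3 were also lost without IAA 2, Dox 1 or Dox 2, and Fgf8 and Ism2 without Dox 1 or Dox 2.

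Most Nodal targets fell and some AhR targets rose in EBd4, and neither list passed with an estimated correlation. Of 12 measured Nodal targets, 0 rose and 8 fell (2 and 9 adjusted over the list alone). Lefty2 (from 479 ± 34.3 to 189 ± 41) and Lefty1 (from 2299 ± 277 to 1277 ± 136) were among the falls. Nodal targets gave adjusted p = 2.59e-07 in the list test and adjusted p = 0.218 with an estimated correlation. Of 7 measured AhR targets, 4 rose and 0 fell (4 and 0 adjusted over the list alone). Tiparp (from 579 ± 19.9 to 1148 ± 65.9, log2 0.99 ± 0.06), Cyp1b1 (ENSMUSG00000024087, chromosome 17, 79701537 to 79715061; from 7.15 ± 3.22 to 34.7 ± 2.84) and Cyp1a1 (from 6.71 ± 1.87 to 27.4 ± 6.58) were among the rises. AhR targets gave adjusted p = 0.000228 in the list test and adjusted p = 0.218 with an estimated correlation. Of 14 measured naive pluripotency genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone). Klf2 (from 199.9 ± 42.2 to 382 ± 45.7) and Tbx3 (0.81) rose and Nanog fell (-0.33). Naive pluripotency genes gave adjusted p = 0.000117 in the list test and adjusted p = 0.218 with an estimated correlation. Of 14 measured primitive streak genes, 0 rose and 5 fell (0 and 6 adjusted over the list alone). The streak gene T (brachyury), named after its values were seen, did not pass, at 1506 ± 638 with Dox and 639 ± 807 with IAA. Primitive streak genes gave adjusted p = 0.00035 in the list test and adjusted p = 0.698 with an estimated correlation. That call was lost without IAA 1. Of 13 measured formative epiblast genes, 0 rose and 2 fell (0 and 4 adjusted over the list alone). Fgf5, a marker of formative epiblast, fell from 1173 ± 68.9 to 739 ± 73.1. Formative epiblast genes gave adjusted p = 0.0297 in the list test and adjusted p = 0.358 with an estimated correlation. Without IAA 3 or Dox 2 that call was lost. Of 16 measured Wnt targets, 1 rose and 2 fell (2 and 7 adjusted over the list alone). Rnf43 rose (1.36) and Ccnd1 fell (-0.22). Wnt targets gave adjusted p = 0.00656 in the list test and adjusted p = 0.698 with an estimated correlation. Without IAA 1 it did not pass.

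The other 15 lists did not pass in EBd4 (adjusted p from 0.0806 to 0.989). Core pluripotency genes had 2 up and 4 down of 12 (4 and 5 adjusted over the list alone), Sox2 among the rises (0.59). FGF and ERK targets had 3 up and 5 down of 16 (5 and 5 adjusted over the list alone), with Dusp4 rising (0.91) and Spred3 falling (-0.53). Stress response genes had 3 up and 0 down of 18 (3 and 0 adjusted over the list alone), Ddit3 among the rises (0.92). Pol II factors had 4 up and 3 down of 41 (4 and 5 adjusted over the list alone). Targets of p53 had 2 up and 2 down of 22 (7 and 3 adjusted over the list alone). Trophoblast genes had 2 up and 0 down of 10 (4 and 1 adjusted over the list alone), Krt18 among the rises (0.94). Definitive endoderm genes had 1 up and 2 down of 9 (1 and 3 adjusted over the list alone), Trh among the falls (-0.99). Primitive endoderm genes had 1 up and 2 down of 14 (2 and 2 adjusted over the list alone). Neuroectoderm genes had 1 up and 1 down of 17 (1 and 2 adjusted over the list alone), Olig2 being the fall (-0.67). Germline genes had 1 up and 0 down of 16 (1 and 0 adjusted over the list alone), Sycp3 being the rise (0.67). Mesoderm genes had 1 up and 0 down of 16 (1 and 0 adjusted over the list alone). Blood and endothelium genes had 1 up and 0 down of 14 (0 and 0 adjusted over the list alone). Fibroblast genes had 0 up and 1 down of 8 (1 and 1 adjusted over the list alone). 2-cell-like genes had 0 up and 0 down of 10 (0 and 0 adjusted over the list alone). Hox genes had 0 up and 0 down of 22 (0 and 0 adjusted over the list alone). The number of EBd4 lists past the threshold, 6, was reached by 4 of the 10 splits of the 6 libraries, the real one included, with 10 lists in the highest other split. The median, mean and test differed in sign for FGF and ERK targets and Hox genes.

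**Figure D2:**
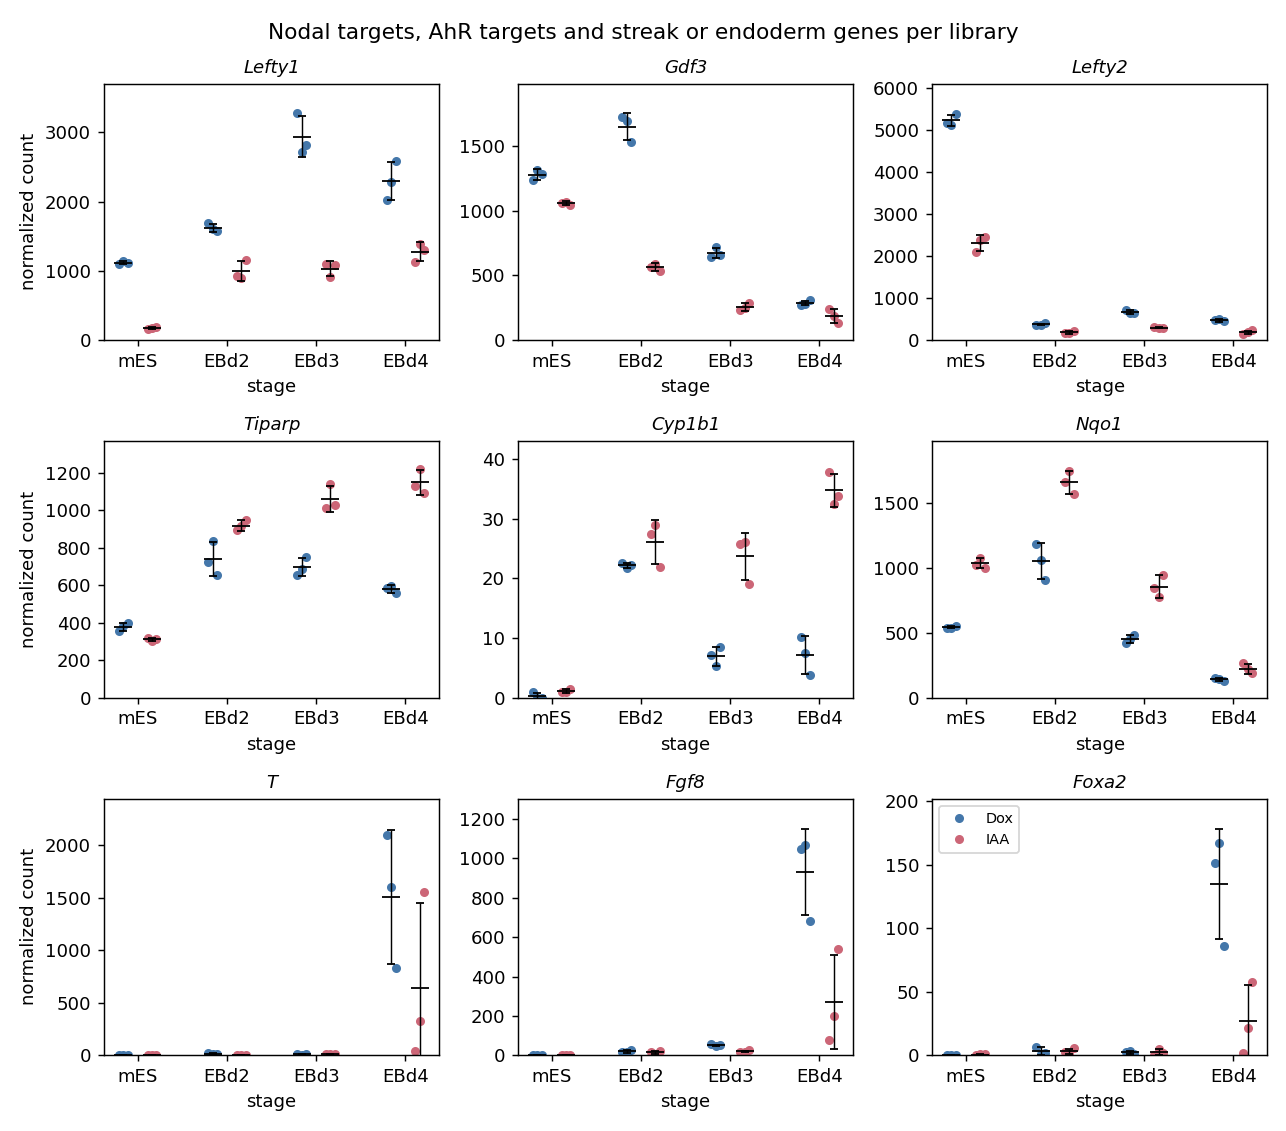
Normalized counts (vertical axes, from 0) of 3 Nodal targets, 3 AhR targets and 3 streak or endoderm genes in each stage (horizontal axes), with libraries as points and the mean ± SD of 3 libraries with Dox (blue) or IAA (red) as bars. Lefty1, Gdf3 and Lefty2 are lower with IAA in EBd3, and the EBd4 IAA libraries spread widely for T and Fgf8.

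Among changes of at least 2-fold, falls outnumbered rises in every stage by limma, edgeR and DESeq2. By limma the falls made up 80.3% in mES, 84.7% in EBd2, 91.0% in EBd3 and 68.3% in EBd4. Over all calls the falls made up 53.7%, 55.5%, 60.0% and 54.3% by limma, but were not a majority in each stage with other scaling or tools. By limma after TMM scaling EBd2 had 3375 rises and 3269 falls and EBd4 1078 and 1046. EBd4 had 1311 rises and 1175 falls by edgeR against 993 and 1180 by limma, and EBd2 had 2453 rises and 2168 falls by DESeq2 against 2954 and 3684 by limma. The table the authors deposited, made with DESeq2 and a 2-fold minimum, listed 102 genes up and 773 down in mES and 125 and 730 in EBd2. It listed 12 up and 158 down in EBd3, and 66 and 144 in EBd4. Of these, 867 of 875, 851 of 855, 170 of 170 and 184 of 210 were past the threshold here with the same sign.

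**Figure D3:**
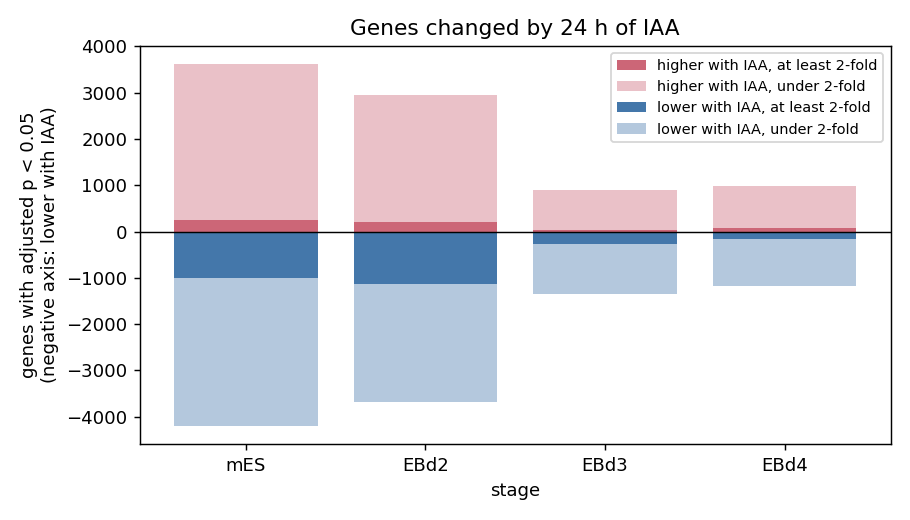
Number of genes past an adjusted p of 0.05 in each stage (horizontal axis), higher with IAA above 0 (red) and lower below 0 (blue), with changes of at least 2-fold in full colour and smaller ones pale. At least 2-fold falls outnumber rises in every stage, 1008 against 247 in mES and 264 against 26 in EBd3.

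Responses common to the stages were counted next. Genes changed in the same direction in all 4 stages numbered 291 of the 18244 tested in each. Of these, 118 rose, against 1.47 expected for independent stages, and 173 fell, against 2.92. That expectation gives every gene the same chance of a call, whatever its level. Genes easier to call in 1 stage may be so in the others, so the size of the excess does not measure the shared response. The largest mean rises were Atf5 (mean log2 1.31), P4ha1 (0.82), Nqo1 (0.79), the neuronal CDK5 activator gene Cdk5r2 (0.76) and LOC100862446 (0.75), annotated as protein-coding. The largest mean falls were the sodium leak channel gene Nalcn (-2.17), the polarity gene Pard3b (-2.02), Trim67 (-1.95), Gpc6 (-1.51) and the acyltransferase gene Mogat2 (-1.51). The number was 159 by DESeq2, 148 without EBd4 Dox 1, 148 without EBd4 Dox 2 and 159 without EBd4 IAA 2. Between pairs of stages, mES and EBd2 shared 1369 rises (561 expected) and 1521 falls (710.3 expected), and EBd2 and EBd3 shared 636 rises (143 expected) and 740 falls (216 expected).

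The Dox cultures alone show how control cells in embryoid bodies differed from control mES cells. The mES cells were kept in 2i medium with LIF and EB formed in medium without LIF. Effects of differentiation and of the change of medium therefore cannot be told apart in these comparisons. Levels here run from mES Dox to the EB Dox groups, and the 3 comparisons share the mES libraries. Naive genes fell, Nanog from 9598 ± 41.5 to 526 ± 53 in EBd2 and Klf4 from 3037 ± 123 to 13.6 ± 2.19 in EBd3. Esrrb went from 8556 ± 187 to 300.3 ± 21.7 in EBd2 and 136 ± 14.9 in EBd4. Of 14 naive pluripotency genes, 0 rose and 13 fell in EBd2, 0 and 13 in EBd3, and 0 and 14 in EBd4. Naive pluripotency genes gave 0 and 14, 0 and 13, and 0 and 14 adjusted over the list alone. Formative genes rose, Dnmt3b from 1047 ± 54.1 to 21015 ± 308, 26262 ± 662 and 16269 ± 1014. Fgf5 was at 0 in mES and at 403 ± 58.4, 696 ± 10.9 and 1173 ± 68.9 in the EB stages. Of 13 formative epiblast genes, 11 rose and 1 fell in EBd2, 10 and 1 in EBd3, and 10 and 3 in EBd4. Formative epiblast genes gave 11 and 1, 10 and 1, and 10 and 3 adjusted over the list alone. Streak genes were high in EBd4, with T going from 3.91 ± 0.553 to 1506 ± 638 and Wnt8a from 0.599 ± 0.520 to 1183 ± 255. Of 14 primitive streak genes, 9 rose and 4 fell in EBd2, 7 and 5 in EBd3, and 10 and 3 in EBd4. Primitive streak genes gave 9 and 4, 7 and 5, and 10 and 3 adjusted over the list alone.

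Signalling and stress genes moved in the Dox cultures as well. Egr1, an immediate early gene, went from 6.33 ± 1.11 to 209 ± 43.6, 379 ± 48.9 and 726 ± 13.1. Of 16 FGF and ERK targets, 14 rose and 1 fell in EBd2, 15 and 0 in EBd3, and 14 and 0 in EBd4. FGF and ERK targets gave 14 and 1, 16 and 0, and 14 and 0 adjusted over the list alone. Ccng1 went from 1034 ± 13.6 to 11370.3 ± 634 and Plk2 from 37.9 ± 3.42 to 2797 ± 438 in EBd2. Of 22 p53 targets, 18 rose and 2 fell in EBd2, 15 and 6 in EBd3, and 11 and 7 in EBd4. Targets of p53 gave 18 and 2, 15 and 6, and 11 and 7 adjusted over the list alone. Of 13 2-cell-like genes, 13 rose and 0 fell in EBd2, 11 and 0 in EBd3, and 5 and 0 in EBd4. 2-cell-like genes gave 13 and 0, 11 and 0, and 5 and 0 adjusted over the list alone. Of 16 germline genes, 14 rose and 2 fell in EBd2, 10 and 3 in EBd3, and 5 and 7 in EBd4. Germline genes gave 14 and 2, 10 and 3, and 5 and 7 adjusted over the list alone. Of 16 Wnt targets, 11 rose and 3 fell in EBd2, 9 and 5 in EBd3, and 13 and 3 in EBd4. Wnt targets gave 11 and 3, 10 and 5, and 13 and 3 adjusted over the list alone. Brd2 itself was at 4497 ± 99.2 in mES, 7409.7 ± 283 in EBd2 and 3015 ± 137 in EBd4. Of 22141 genes tested by limma, 14190 changed in EBd2 (7748 up, 6442 down), 13300 in EBd3 (6967 up, 6333 down) and 13461 in EBd4 (6776 up, 6685 down). At least 2-fold changes numbered 7150, 6424 and 6648.

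The remaining lists in the Dox cultures were counted in the same way. Of 12 core pluripotency genes, 7 rose and 4 fell in EBd2, 3 and 8 in EBd3, and 4 and 7 in EBd4. Core pluripotency genes gave 7 and 4, 3 and 8, and 4 and 7 adjusted over the list alone. Of 19 neuroectoderm genes, 7 rose and 5 fell in EBd2, 8 and 4 in EBd3, and 8 and 5 in EBd4. Neuroectoderm genes gave 7 and 5, 8 and 4, and 9 and 5 adjusted over the list alone. Of 15 mesoderm genes, 7 rose and 3 fell in EBd2, 5 and 3 in EBd3, and 7 and 2 in EBd4. Mesoderm genes gave 7 and 3, 5 and 3, and 7 and 2 adjusted over the list alone. Of 14 blood and endothelium genes, 8 rose and 1 fell in EBd2, 9 and 3 in EBd3, and 7 and 4 in EBd4. Blood and endothelium genes gave 9 and 1, 9 and 3, and 7 and 4 adjusted over the list alone. Of 15 primitive endoderm genes, 8 rose and 3 fell in EBd2, 8 and 5 in EBd3, and 9 and 5 in EBd4. Primitive endoderm genes gave 8 and 3, 8 and 5, and 9 and 5 adjusted over the list alone. Of 10 definitive endoderm genes, 4 rose and 2 fell in EBd2, 5 and 2 in EBd3, and 6 and 3 in EBd4. Definitive endoderm genes gave 4 and 2, 5 and 2, and 6 and 3 adjusted over the list alone. Of 10 trophoblast genes, 5 rose and 4 fell in EBd2, 5 and 3 in EBd3, and 6 and 4 in EBd4. Trophoblast genes gave 5 and 4, 6 and 3, and 6 and 4 adjusted over the list alone. Of 34 Hox genes, 15 rose and 11 fell in EBd2, 10 and 13 in EBd3, and 7 and 13 in EBd4. Hox genes gave 15 and 12, 10 and 13, and 7 and 13 adjusted over the list alone. Of 9 AhR targets, 7 rose and 1 fell in EBd2, 5 and 2 in EBd3, and 4 and 2 in EBd4. AhR targets gave 7 and 1, 5 and 2, and 4 and 2 adjusted over the list alone. Of 12 Nodal targets, 6 rose and 3 fell in EBd2, 4 and 7 in EBd3, and 6 and 4 in EBd4. Nodal targets gave 6 and 3, 4 and 7, and 6 and 4 adjusted over the list alone. Of 41 Pol II factors, 23 rose and 12 fell in EBd2, 17 and 13 in EBd3, and 13 and 17 in EBd4. Pol II factors gave 25 and 12, 17 and 15, and 13 and 17 adjusted over the list alone. Of 18 stress response genes, 7 rose and 10 fell in EBd2, 8 and 5 in EBd3, and 6 and 10 in EBd4. Stress response genes gave 7 and 10, 8 and 5, and 6 and 10 adjusted over the list alone. Of 10 fibroblast genes, 8 rose and 0 fell in EBd2, 7 and 0 in EBd3, and 7 and 0 in EBd4. Fibroblast genes gave 8 and 0, 7 and 0, and 7 and 0 adjusted over the list alone.

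Whether the IAA effect differed between stages was tested directly, as the IAA change in an EB stage minus that in mES (log2 difference). Since the medium also differs between mES and EB, a difference may belong to the stage or to the medium. Porcn, which fell in mES, had differences of 3.83 in EBd2, 4.28 in EBd3 and 3.16 in EBd4, and Enpp3 of 3.23 in EBd2 and 3.04 in EBd3. Ramp3 had 3.26, 3.05 and 3.01. Spry4 had 3.43 in EBd2, Arhgef5 3.46 in EBd3, and Atp2c2 3.17 and Gadd45g 2.99 in EBd4. On the negative side stood Tmem132d (-2.54, -3.52 and -4.24), with Fst (-2.99), Foxn4 (-2.58) and Ccdc187 (-2.56) in EBd2. Ptprt (-2.93), Il17f (-2.73) and Gsc (-2.51) did so in EBd3, and Gsc (-3.33), Fst (-3.44) and Foxa2 (-3.64) in EBd4. The epiblast gene Dnmt3b had positive differences in all 3 stages (2.13, 1.67 and 1.57). Lin28a, of the core pluripotency list, did as well (1.23, 1.23 and 1.24). The rise of Brd2 was smaller in the EB stages, with differences of -0.22, -0.49 and -0.39. Of 22019 genes tested by limma, 3599 differed in EBd2 (2143 higher and 1456 lower than in mES), 2570 in EBd3 (1575 and 995) and 3690 in EBd4 (2131 and 1559). This fit takes the spread of a gene from all 24 libraries, although library pairs differed more in EBd4 IAA than in mES. Chi-square per degree of freedom reached 5.35 in EBd4 IAA and 1.48 in mES. With that shared spread, IAA calls went from 2173 to 3425 in EBd4 and from 7821 to 5820 in mES. The 3 counts therefore do not rank the stages, and calls in EBd4 may be too many.

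By list, 6 differences from mES passed in EBd2. Naive pluripotency genes had a median difference of -0.99, with adjusted p = 2.46e-07 and adjusted p = 0.0439 with an estimated correlation. Formative epiblast genes had a median difference of 0.25, with adjusted p = 2.46e-07 and adjusted p = 0.0439 with an estimated correlation. Germline genes had a median difference of -0.45, with adjusted p = 0.00327 and adjusted p = 0.151 with an estimated correlation. FGF and ERK targets had a median difference of 0.32, with adjusted p = 0.0112 and adjusted p = 0.0993 with an estimated correlation. Pol II factors had a median difference of -0.06, with adjusted p = 0.0298 and adjusted p = 0.28 with an estimated correlation. Neuroectoderm genes had a median difference of 0.41, with adjusted p = 0.0395 and adjusted p = 0.151 with an estimated correlation.

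In EBd3, 10 lists differed from mES. Stress response genes had a median difference of -0.58, with adjusted p = 9.74e-08 and adjusted p = 0.0456 with an estimated correlation. Hox genes had a median difference of -0.85, with adjusted p = 0.00148 and adjusted p = 0.0194 with an estimated correlation. Nodal targets had a median difference of -0.56, with adjusted p = 0.00663 and adjusted p = 0.0561 with an estimated correlation. Trophoblast genes had a median difference of 0.39, with adjusted p = 0.0101 and adjusted p = 0.0456 with an estimated correlation. Naive pluripotency genes had a median difference of -0.34, with adjusted p = 0.0222 and adjusted p = 0.307 with an estimated correlation. Germline genes had a median difference of -0.22, with adjusted p = 0.0101 and adjusted p = 0.278 with an estimated correlation. FGF and ERK targets had a median difference of 0.08, with adjusted p = 0.0167 and adjusted p = 0.0935 with an estimated correlation. Pol II factors had a median difference of -0.07, with adjusted p = 0.00218 and adjusted p = 0.15 with an estimated correlation. Formative epiblast genes had a median difference of -0.15, with adjusted p = 0.0167 and adjusted p = 0.278 with an estimated correlation. Definitive endoderm genes had a median difference of -0.03, with adjusted p = 0.0101 and adjusted p = 0.0714 with an estimated correlation. The last pair had a negative median while the mean and the test were positive.

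In EBd4, 6 lists differed from mES. Stress response genes had a median difference of -0.24, with adjusted p = 4.85e-06 and adjusted p = 0.0547 with an estimated correlation. Pol II factors had a median difference of -0.13, with adjusted p = 5.25e-06 and adjusted p = 0.0547 with an estimated correlation. Targets of p53 had a median difference of 0.30, with adjusted p = 0.000569 and adjusted p = 0.441 with an estimated correlation. Primitive streak genes had a median difference of -1.42, with adjusted p = 0.003 and adjusted p = 0.441 with an estimated correlation. Trophoblast genes had a median difference of 0.74, with adjusted p = 0.00539 and adjusted p = 0.0468 with an estimated correlation. Hox genes had a median difference of -0.64, with adjusted p = 0.00539 and adjusted p = 0.0468 with an estimated correlation.

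Genomic span was set beside the IAA change for protein-coding genes with a mean of at least 20 normalized counts. In EBd3, the 260 genes spanning more than 300 kb had a median log2 change of -0.62, and 73.8% of them fell and 0.385% rose. The 2747 genes under 10 kb had a median of 0.02. In EBd4 the 272 longest had a median of -0.36 with 42.6% falling, in EBd2 the 268 longest -0.15 with 36.6% falling, and in mES the 202 longest -0.13 with 39.1% falling. Of genes under 10 kb, 27.7% fell in mES and 20.7% in EBd2, against 5.97% in EBd3 and 7.81% in EBd4. The shares of the longest genes in mES and EBd2 thus stand beside higher general shares of falls. In mES, EBd2 and EBd4 only the classes over 100 kb had medians below that of genes under 10 kb, and genes of 30 to 100 kb lay above it (0.01 against -0.01 in mES, 0.02 against 0.01 in EBd2 and 0.00 against -0.04 in EBd4). Genes are not independent replicates, so no p is given across them, and the slope was taken per library. In EBd3, the slope of a library's log2 level relative to the Dox mean, per 10-fold of span with exonic length and level in the model, was -0.21, -0.23 and -0.17 in the 3 IAA libraries. It was 0.02, -0.01 and -0.01 in the 3 Dox libraries. Each Dox library was set against the mean of the other Dox libraries, so their slopes balance around 0 by construction and show only their spread.

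**Figure D4:**
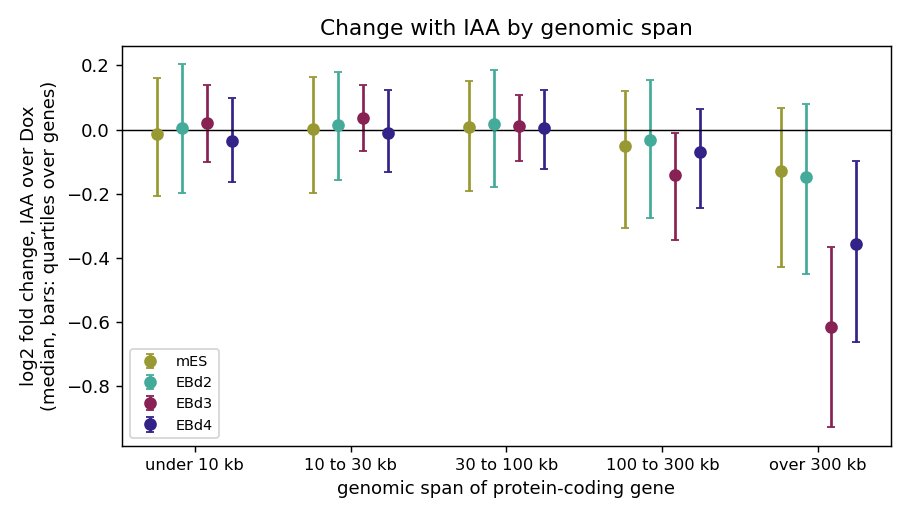
Median log2 fold change of IAA over Dox (vertical axis, bars are the quartiles over genes) of protein-coding genes in 5 classes of genomic span (horizontal axis), for each stage. The class over 300 kb lies lowest in every stage, at -0.62 in EBd3.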

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

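Among the tests in this part, those of Nrf2 targets, of IAA as a compound and of 1 IAA library alone were chosen only after the result was seen, and the margin of 1 SD of the Dox libraries in the span and 1 IAA library tests was added after their values were seen. The next 3 paragraphs give differences between stages, the IAA effect in an EB stage minus that in mES, past the threshold of a test of the difference itself (limma for genes, camera of limma for lists). After them come weighed patterns and counts of splits. Groups of 3 were not searched by a rule for single outlying libraries, although library pairs were compared and EBd2 Dox 3 stood apart.

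In EBd2, 3599 genes had a different IAA effect than in mES, and 635 of them were called in both stages with opposite signs (373 up in EBd2, 262 down). Over the 18244 genes tested in each stage, opposite calls numbered 640, fewer than the 1263 expected for independent stages. List medians differed by -0.99 for naive pluripotency, 0.25 for formative epiblast, 0.41 for neuroectoderm, -0.45 for germline, 0.32 for FGF and ERK targets and -0.0583 for Pol II factors. With an estimated correlation, neuroectoderm (adjusted p = 0.151), germline (0.151), FGF and ERK targets (0.0993) and Pol II factors (0.28) were not past the threshold. Named genes with opposite calls and positive differences were Enpp3 (3.23), Tiparp (0.60), Cldn6 (1.48), Spry4 (3.43), Dnmt3b (2.13), Dnmt3a (1.49), Zic2 (1.35), Krt8 (1.09), Krt18 (1.06), Pax6 (2.52) and Sox2 (0.75). Negative ones were Tfcp2l1 (-0.86), Esrrb (-1.21), Nanog (-1.23), Fbxo15 (-1.48) and Nodal (-1.08). The Spry4 call in EBd2 was lost by edgeR and DESeq2.

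In EBd3, 2570 genes differed from mES, 157 of them with opposite calls (82 up in EBd3, 75 down). Among the 18244 genes tested in each stage there were 161 opposite calls, fewer than the 438 expected for independent stages. List medians differed by -0.34 for naive pluripotency, -0.15 for formative epiblast, -0.0264 for definitive endoderm, 0.39 for trophoblast, -0.22 for germline, -0.85 for Hox genes, 0.0758 for FGF and ERK targets, -0.56 for Nodal targets, -0.0697 for Pol II factors and -0.58 for the stress response. With an estimated correlation, only trophoblast, Hox genes and the stress response stayed past the threshold, and 7 lists did not: naive pluripotency (adjusted p = 0.307), formative epiblast (0.278), definitive endoderm (0.0714), germline (0.278), FGF and ERK targets (0.0935), Nodal targets (0.0561) and Pol II factors (0.15). For formative epiblast and definitive endoderm the test pointed up, as did the means (0.21 and 0.32), against the sign of the medians. Opposite calls included Enpp3 (3.04), Porcn (4.28), Tiparp (0.89), Cldn6 (1.07), Spry4 (3.04) and Hspa5 (0.28) on the positive side. On the negative side were Tmem132d (-3.52), Nanog (-0.70) and Fbxo15 (-0.69). The Nanog call in EBd3 was lost by edgeR and DESeq2.

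In EBd4, 3690 genes differed from mES, 291 of them with opposite calls (172 up in EBd4, 119 down). Opposite calls were again fewer than expected for independent stages, 290 against 431 over the 18244 genes tested in each stage. List medians differed by -1.42 for the primitive streak, 0.74 for trophoblast, -0.64 for Hox genes, 0.30 for p53 targets, -0.13 for Pol II factors and -0.24 for the stress response. With an estimated correlation, primitive streak (adjusted p = 0.441), p53 targets (0.441), Pol II factors (0.0547) and the stress response (0.0547) were not past the threshold. Opposite calls with positive differences were Tiparp (1.27), Utf1 (1.59), Cldn6 (1.06), Krt18 (1.66), Gadd45g (2.99), Sox2 (0.66), Spry1 (0.99), Pax6 (1.97) and Trp53inp1 (0.54). Negative ones were Tmem132d (-4.24), Olig2 (-0.94), Gsc (-3.33) and Nanog (-0.54).

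Genes spanning over 100 kb had lower log2 fold changes with IAA than genes under 10 kb, while in mES, EBd2 and EBd4 genes of 30 to 100 kb did not, and the rank correlation with span in mES was -0.0337. With exonic length and level in the model, the slope per 10-fold of span was -0.118 in mES, -0.202 in EBd3 and -0.0777 in EBd4. Every IAA library lay below every Dox library by more than the SD of the Dox libraries. The slope on exonic length, fitted beside span, was itself positive (0.182, 0.131 and 0.0156). Taken alone, the rank correlation of the change with exonic length was 0.105 in mES, -0.0645 in EBd3 and -0.0208 in EBd4. In mES both values argue against a bias that lowers long transcripts. In EBd3 and EBd4 the slope and the rank correlation differ in sign, so they do not settle such a bias. A length bias of the other sign is not excluded, since Dox libraries cannot show a bias that differs with IAA. Span and exonic length also go together (rank correlation 0.658 in mES). In mES the rank correlation of the change had opposite signs for exonic length and for span, so its span slope depends on fitting both. Among genes with at least 200 counts the slope was -0.0929 in mES and -0.121 in EBd3, again beyond that SD, which argues against low expression of long genes in these 2 stages. In EBd2 neither a bias that lowers long transcripts nor low expression can be excluded (-0.103, and -0.0577 at 200 counts). There the Dox libraries reached -0.0574 and -0.0437. The IAA libraries began at -0.0913 and -0.0448, within the Dox SD of 0.0508 and 0.0387. Low expression cannot be excluded in EBd4 either (-0.0332, short of the bound of -0.05). No table here addresses elongation, and whether it is lower along these genes is a candidate explanation that nascent RNA profiling with and without IAA would test.

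With IAA 3 of 8 AhR targets rose in EBd3 and 4 of 7 in EBd4, and the list did not pass with an estimated correlation (adjusted p = 0.156 and 0.218). Both counts include Nqo1, which rose in all 4 stages (mean log2 0.79) and so is not particular to EBd3 and EBd4. If a general oxidative stress response were the cause, the Nrf2 targets Hmox1, Gclm, Gclc, Srxn1, Txnrd1 and Slc7a11 would rise, and their EBd4 median was 0.375, with 4 of 6 past the threshold. The medians were nearly as high in mES (0.29) and EBd2 (0.27), where the AhR list did not pass, and 0.31 in EBd3, so it cannot be told apart, as the values point both ways. The first bound asked only that the median lie below 0.5 by more than its spread over the IAA libraries (0.0811), under which this explanation was argued against, and after that outcome was seen it was changed to ask also that fewer than 3 members rise. IAA acting as a compound, apart from BRD2 loss, may raise these genes too, and it cannot be told apart, since 0 libraries from cells without the degron received IAA.

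Of 14 primitive streak genes 5 fell with IAA in EBd4, varying between libraries, and the list did not pass with an estimated correlation (adjusted p = 0.698). The list median against the Dox mean was -2.95, -1.72 and 0.27 in the 3 IAA libraries and 0.32, 0.22 and -0.67 in the Dox libraries. Without each IAA library in turn the list median of IAA over Dox was -0.711, -1.72 and -2.56, the first without IAA 1 and within the Dox SD (0.544) of the bound of -0.5, so 1 IAA library alone cannot be told apart. For a delay of the whole day 3 to day 4 programme, genes that rose between those days in Dox lay at 0.292, 0.57 and 0.797 of the way in the IAA libraries, against 1.02, 1.01 and 0.899 in the Dox libraries. Genes that fell lay at 0.807, 0.856 and 0.938, against 0.894, 0.922 and 0.894, so 1 of the 3 IAA libraries reached the lowest Dox library (0 on a first scale that included the placed library, replaced after its value was seen) and a delay may account for part of it but cannot be told apart.

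Splits of the libraries were counted as well. For IAA against Dox, 3 against 3 gives 10 splits, too few for a share under 0.05. The real split gave 7821, 6638, 2245 and 2173 genes in the 4 stages, was alone in giving as many (1 of 10 in each), and the highest other split gave 0 by limma. Every other split puts Dox and IAA libraries into both groups, so the IAA effect widens the spread within them. The 0 therefore does not settle chance. For lists, the real values of 6, 15 and 8 in mES, EBd2 and EBd3 stood against 4, 7 and 5 in the highest other split (1 of 10 each). In EBd4 4 of 10 splits reached the real 6, with 10 in the highest other. The median of the other splits was 2, 4, 2 and 5 lists in the 4 stages. Those splits mix Dox and IAA libraries unevenly, so they can hold part of the IAA effect. For the Dox stages the real split was also 1 of 10, with 14190, 13300 and 13461 genes against 0. The other splits mix the stages in the same way, so that 0 does not settle chance either. For the differences between stages, 2 of 100 splits gave as many as the real 3599 in EBd2 (highest other 7718), 8 as many as 2570 in EBd3 (3803) and 4 as many as 3690 in EBd4 (5996). The other splits that reached these counts all kept the true mES groups (1, 7 and 3 of them) and so hold the mES effect of IAA, which is why these shares do not settle whether chance can be excluded. Among the 75, 77 and 82 splits with neither stage's true groups the highest count was 1 gene. There too the IAA effect widens the spread within groups, so this count does not settle chance. For genes changed in all stages, 1 of 100 splits gave the real 291 (highest other 0). Since wrong splits within a single stage gave 0 genes, this outcome was fixed beforehand and does not settle chance.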

How the results depend on the processing

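Among the alternatives, TMM scaling with edgeR or limma and a pseudocount of 0.1 with the filter kept were chosen only after the result was seen. No alternative moved the median of all genes by over 0.1, and 0 genes were called in the opposite direction by another setting within a comparison. With an absolute log2 fold change of at least 1, counts were 1255, 1342, 290 and 240 for IAA in the 4 stages, 7150, 6424 and 6648 for the Dox stages, 912, 710 and 928 for the differences between stages, and 5 in all stages, as that alternative by construction keeps fewer genes. DESeq2 gave 1214 genes in EBd3, 1413 in EBd4 and 159 in all stages, and of the 7821 limma calls in mES it kept 5213. The cause was not tested. The fit of all 24 libraries gave 3425 genes in EBd4, and the cause was not tested. With the list correlation estimated per list, 0 lists passed in mES, 0 in EBd2, 1 in EBd3 and 0 in EBd4, and the cause was not tested. Leaving out each library in turn gave 1202 to 2613 genes in EBd3, 776 to 2039 in EBd4, 148 to 315 in all stages and 5 to 9 lists in EBd3. Some of these counts rose, and the cause was not tested. The replicate block gave 1365 genes in EBd4 against 2173. Own-number correlations there were -0.20, 0.03 and -0.29, so the samples share only a number, and the cause was not tested. Of values of named genes under IAA with a library left out, 1431 stayed on their side of the threshold, 126 lost their call and 3 gained one. The stage difference (Cyp1b1, IAA effect differs, EBd4 against mES) turned to -0.0931 with a pseudocount of 0.1, both with and without the filter, and the cause was not tested. With simulated changes of 1.5-fold, recovery was 63 of 100 in EBd4 and 69 in mES, and recovery by read number was not tabulated.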

Other observations

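All gene families in this part, and the tests on them, were chosen only after the result was seen. Most genes of a glycolysis and hypoxia family rose in EBd2. Of 19 measured, 14 rose and 1 fell, with adjusted p = 2.22e-13 by camera and adjusted p = 0.0228 with an estimated correlation. The glucose transporter gene Slc2a1 went from 1925 to 3812 (log2 0.99 ± 0.07), Pgk1 from 4230.1 to 6631 (0.65 ± 0.04) and Aldoa from 5206 to 7921 (0.61 ± 0.05). In mES 9 rose and 6 fell, in EBd3 10 rose and 0 fell, and in EBd4 8 rose and 1 fell, and with an estimated correlation the family did not pass in these 3 stages (adjusted p = 0.411, 0.312 and 0.456). The mitochondrial mitophagy gene Bnip3 moved from 389 to 220.2 in mES (-0.82 ± 0.07) and from 261 to 488 in EBd2 (0.90 ± 0.07).

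Several genes of cholesterol synthesis changed, and as a family they did not pass with an estimated correlation in any stage. Of 18 measured, 1 rose and 10 fell in mES, 11 rose and 1 fell in EBd2, 0 rose and 11 fell in EBd3, and 1 rose and 11 fell in EBd4. With an estimated correlation the adjusted p of the limma list test was 0.152, 0.223, 0.199 and 0.238. Hmgcs1, an early enzyme of the pathway, fell from 3318 to 2329.8 in EBd3 (log2 -0.51 ± 0.05) and from 3338 to 2418 in EBd4 (-0.47 ± 0.06). Of 77 cytosolic ribosomal protein genes, 47 rose and 7 fell in mES and 31 rose and 5 fell in EBd2 (adjusted p = 0.299 and 0.595 with an estimated correlation). Only 7 rose and 6 fell in EBd3, and 3 rose and 0 fell in EBd4. Of nuclear genes of oxidative phosphorylation, 7 rose and 44 fell of 92 in mES (adjusted p = 0.225 with an estimated correlation). In EBd2 9 rose and 26 fell of 91, in EBd3 1 and 7 of 91, and in EBd4 1 and 6 of 90. Of 41 collagen genes measured in EBd2, 3 rose and 16 fell (adjusted p = 0.14 with an estimated correlation). In mES 5 rose and 11 fell of 29, in EBd3 0 and 5 of 39, and in EBd4 2 and 8 of 38.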
